A study of Rattus norvegicus with 9 samples.

How the data were processed

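Poly(A)-selected RNA from the hippocampus of 9 male rats was sequenced, with 1 library per rat and 3 rats in each of 3 groups. The control rats were fed normally. The other rats had middle cerebral artery occlusion, a surgical model of ischaemic stroke, and entered the study when both their alternation rate and their cognitive index lay under a limit given as 20% of the control mean. They were then randomly assigned to a group with post-stroke cognitive impairment (PSCI) that was fed normally for 2 weeks or to a group given transcutaneous auricular vagus nerve stimulation (taVNS), an electrical stimulation of the vagal branch in the outer ear, for 14 days. The labels do not say whether the controls had sham surgery, which hemisphere was taken, or whether the PSCI rats had sham stimulation. The extraction text speaks of mice, while every label gives the rat, and the gene symbols and identifiers in the files are those of the rat.

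Each library came with a table of gene counts and a table of RPKM. The gene counts are the authors' expected counts (reads assigned to a gene by a model, not scaled for depth or length). The RPKM values, reads scaled for gene length and depth, are deposited by the authors with 2 decimals. Per the submitters' processing notes HISAT2 2.0.4 and RSEM 1.2.8 were used with the genome build mRatBN7.2, and the notes do not give the role of each tool, the annotation or any filter. Both tables hold 18733 genes with an NCBI gene identifier. Between 91.1% and 91.6% of the genes had an exactly whole count in a library. A reference table of the newer assembly GRCr8 was used for names and numbers of transcripts alone: 18486 of the identifiers were found in it, 16803 with the same symbol, and 18240 as protein coding. No genome positions are given, since the table's build is not the one the authors used.

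The estimated counts were rounded to whole numbers. Total counts ran from 13747389 to 15415694 per library, so a count of 0 in a library allows a level of up to 0.195 to 0.218 CPM (counts scaled to library size), taking a floor of 3 counts. Intervals at the 95% level (exact binomial) and floors cover counting error only, because reads without molecular identifiers are not independent molecules. Genes were kept by the filterByExpr function of edgeR 4.0.16 (14840 genes), scaled by the trimmed mean of M values (TMM), and tested with the quasi-likelihood F test of edgeR in a fit of all 9 libraries on group, with 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold limit. Fold changes are given on the log2 scale with their standard error (SE), and levels as CPM after TMM scaling, as mean and standard deviation (SD) of 3 libraries. R 4.3.3 and limma 3.58.1 were used, and log2 CPM used a prior count of 2. Where a group held 3 counts or fewer for a named gene, a ratio with its counting interval or a bound against 3 counts over the group is given in place of the fitted fold.

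The tests, the comparisons, 29 gene lists and the rule for naming genes were set before the data were examined. The lists hold 456 genes, of which 448 were found in the tables, 2 of them under another symbol, and 420 passed the filter. They cover excitatory neurons, dentate granule cells, inhibitory interneurons, synaptic vesicle and postsynaptic scaffold, microglia and macrophages, reactive astrocytes, homeostatic astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelium and pericytes, choroid plexus and ependyma, meninges and fibroblasts, thalamus and habenula, striatum, neocortex, red blood cells, immediate early genes, cytokines and NF-kB targets, interferon response and antigen presentation, acetylcholine signalling, monoamine receptors and transporters, neurogenesis and cell division, neurotrophic and growth factors, glucocorticoid response, circadian clock, heat shock and unfolded protein response, oxidative phosphorylation, apoptosis and autophagy, and hypoxia and glycolysis. Each list was tested against all other genes with camera of limma at the preset correlation of 0.01, with adjustment over the 29 lists within a comparison, and again with a correlation estimated from the data. With an estimated correlation camera also judges its statistic on the 6 residual degrees of freedom, not on the number of genes. A call lost in that setting therefore need not be due to correlation among the members. Called members are counted after adjustment over all genes and after adjustment over the list alone.

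For each comparison the named genes are the 12 largest rises and 12 largest falls among called genes whose 3 values in a group all lie above, or all below, the 3 of the other group and whose mean is at least 1 CPM, leaving out symbols of unnamed loci. In PSCI against control 1460 of the 1461 called genes were separated in this way and 1383 were eligible, with 32 unnamed loci left out, and in taVNS against PSCI 853 of 854 were separated, 812 were eligible and 17 were left out. Over all tested genes the groups did not overlap for 27.4% in PSCI against control, 25.9% in taVNS against PSCI and 11.2% in taVNS against control, where chance gives 10%. The rule adds up to 4 called members of each list, up to 2 members with the smallest p of a list with none, the 12 genes past both thresholds in opposite directions with the smallest larger p, and 9 markers fixed for every comparison (Gfap, Aif1, Cd68, Mbp, Bdnf, Chrna7, Slc17a7, Gad1 and Ttr). A few genes that the rule gives are left out of the text. Further list members and other genes outside the rule are named as examples and were chosen after their values were seen.

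The deposited counts and RPKM were also compared with each other. The log2 ratio of count to RPKM was centred on its median in each library, for the 13601 genes with at least 10 counts and an RPKM of at least 0.1 in every library. A gene was said to disagree in a set of 3 libraries when each of the 3 deviated from the median of the other 6 by more than any of those 6 did, and the median deviation passed 0.25 (log2), or 0.5 for a stricter count. This comparison and its limits were chosen after the data were seen, and limits between 0.25 and 0.5 were looked at.

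The alternatives tried were the size factors of DESeq2, DESeq2 1.42.0 and limma-voom as tests, no filter, a stricter filter (at least 1 CPM in at least 3 libraries and 50 counts in all), a fit of only the 6 libraries compared, the replicate number as a block, a robust fit, a log2 fold limit of 1, limma on log2 RPKM with 0.1 added (and with 1 added for taVNS against PSCI), leaving out each library in turn, an estimated correlation for the lists and, added after the data were seen, leaving out the genes whose counts and RPKM disagree before the adjustment of p. The replicate numbers did not pair the libraries: after removal of the group means, 2 of the 9 same-numbered pairs correlated above 0.1 across genes (range -0.468 to 0.255), and 1 of 9 libraries had its highest correlation with its own number.

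The procedure was tested on simulated data with the dispersions of these libraries, in 5 sets with 200 changed genes each, shared among 3 folds. In PSCI against control it called 11.1% of genes changed 1.5-fold, 53.9% of those changed 2-fold and 86.5% of those changed 4-fold, and 3.85% of its calls were unchanged genes. In taVNS against PSCI these were 10.5%, 53.3%, 88.1% and 5.11%. In taVNS against control, simulated without a change, 1 gene was called over the 5 sets, so no detection rate is known for this comparison. The shares found also depend on how many genes change. In the data 1461 genes were called in PSCI against control, where 200 were simulated, so these shares may not carry over. A shifted list was called in 5 of 5 sets, no unshifted list was called (0 in all), and the comparison of counts with RPKM found 30 of 30 altered genes. The simulated genes were drawn independently, while list members in the data had estimated correlations of up to 0.848 (meninges and fibroblasts). The list result therefore does not show how often camera calls unchanged lists of correlated genes. The altered genes had a ratio shifted by 1 (log2) in all 3 libraries of a group, so smaller disagreements were not tried.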

Results

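The data are gene counts and RPKM of hippocampal RNA from 9 rats, with 3 libraries each from control rats, rats with post-stroke cognitive impairment (PSCI) after middle cerebral artery occlusion, and impaired rats given transcutaneous auricular vagus nerve stimulation (taVNS). The libraries held from 13747389 counts (control replicate 3) to 15415694 counts (PSCI replicate 3). On the first principal component of log2 CPM, which held 48.2% of the variance, the control libraries lay at -30.3, -29.6 and -36.2, the taVNS libraries at -24.5, -19.5 and -7.41, and the PSCI libraries at 19.7, 74.9 and 52.8. The PSCI libraries differed most among themselves, with a median SD per gene of 0.217 (log2), against 0.167 in control and 0.149 in taVNS. Markers of meninges and fibroblasts, tissue that can adhere to a dissected hippocampus, stood apart in PSCI replicate 2 and taVNS replicate 3, where the list averaged 4.81 and 5.12 log2 CPM, while the other 7 libraries lay between 2.1 and 2.97.

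The deposited counts and the deposited RPKM gave different answers for some genes in the PSCI libraries. Among 13601 genes examined, 47 disagreed by more than 0.25 (log2) in the PSCI set, against 6 in the control set and 2 in the taVNS set, and the highest of the other sets of 3 libraries had 13. Past 0.5 there were 22 genes in the PSCI set, 0 in control and 0 in taVNS, and at most 3 in any other set. Of these 22, 18 were higher in PSCI by counts past the threshold, among them Casp9, Becn1, Ulk1, Map1lc3a, Rb1cc1, Traf6, Nfkb1 and Ikbkb, and 1, Sqstm1, was lower. Bcl2, an inhibitor of apoptosis, rose by 2.32 (log2) in counts while its RPKM fell by 2.20, and Gabarapl2, a protein of the autophagosome membrane, rose by 1.85 in counts while its RPKM fell by 0.29. Casp9, the initiator caspase of the mitochondrial pathway, had a log2 ratio of PSCI to control of 2.00 in counts and 0.92 in RPKM, and Map1lc3a, an autophagosome protein, 2.21 and 0.71. The 47 genes held 8 of the 17 examined members of the apoptosis and autophagy list, 12 of 380 examined members of all lists, and 15 of the 20 genes with the smallest p in both PSCI against control and taVNS against PSCI. The files do not show which of the values came from the reads, so the size of change of these 47 genes is not settled by the data. Nor is the direction for 9 of the 47, whose ratio of PSCI to control had opposite signs in counts and RPKM. Of these 9, 3 were called by counts: Bcl2, Gabarapl2 and Pdk3 (log2 ratio -0.35 in counts and 0.11 in RPKM). With the 47 genes left out before the adjustment of p, 1420 and 820 genes were called in these comparisons.

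**Figure D1:**
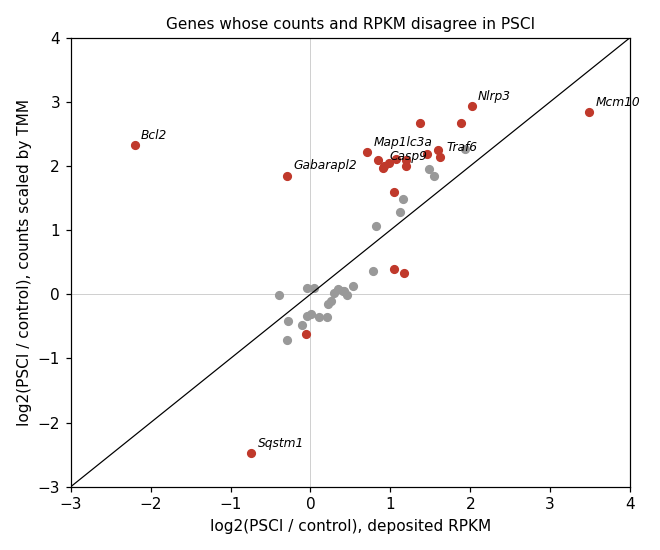
Log2 ratio of PSCI to control from the deposited RPKM (x axis) against the same ratio from counts scaled by TMM (y axis) for the 47 genes whose counts and RPKM disagree in the PSCI libraries, each point a gene and each ratio from means of 3 libraries. Red points are the 22 genes past 0.5 and grey points the rest; points on the diagonal would have the same ratio in both, and Bcl2 has 2.32 in counts and -2.20 in RPKM.

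The comparison of PSCI with control asks what differs in the hippocampus of rats impaired after stroke. Of the gene lists, 11 of 15 reactive astrocyte, 13 of 18 microglia, 9 of 11 cytokine and 8 of 14 cell division genes rose in PSCI, and 5 of 20 immediate early genes fell. With an estimated correlation none of these 5 lists was called (adjusted p = 0.15 to 0.34). Gfap, the intermediate filament of astrocytes, rose from 946 ± 288 to 6110 ± 1830 CPM (SD, n = 3), and Vim, another filament protein of reactive glia, from 25.5 ± 3.86 to 860 ± 404 CPM. Top2a, the topoisomerase of dividing cells, rose from 1.83 ± 0.288 to 60.5 ± 38.9 CPM, and C1qb, a chain of complement C1q made by microglia, from 29.0 ± 5.44 to 124 ± 25.5 CPM. Egr2, an activity-dependent transcription factor, fell from 9.14 ± 0.891 to 1.08 ± 0.72 CPM. In all, 1461 of 14840 genes passed the test, 1144 higher and 317 lower in PSCI, and 832 of the higher and 45 of the lower ones changed at least 2-fold. The count changed with the libraries: it was 922 without control replicate 1, 635 without control replicate 2, 548 without control replicate 3, 2255 without PSCI replicate 1 and 785 without PSCI replicate 3. DESeq2 called 2278 genes, 1586 higher and 692 lower, and limma on log2 RPKM with 0.1 added called 1133 higher and 174 lower.

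**Figure D2:**
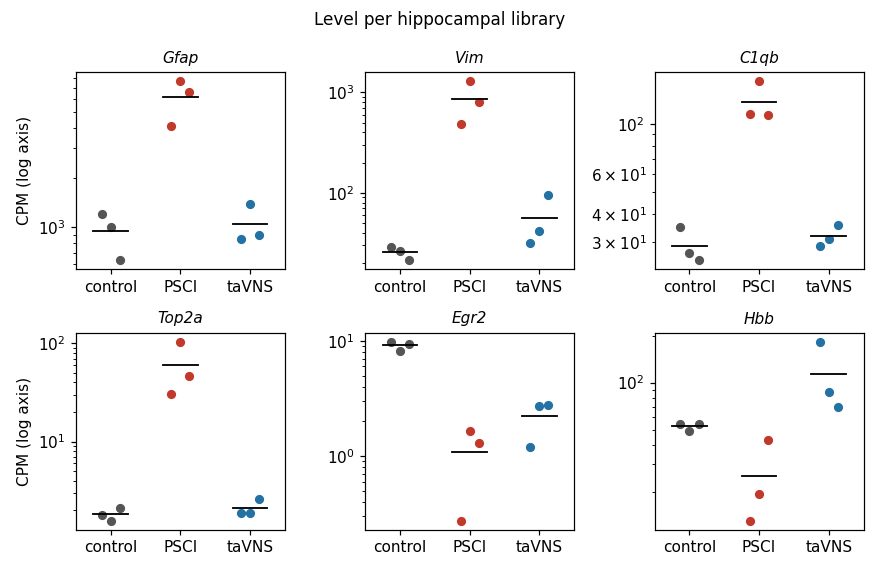
Level of Gfap, Vim, C1qb, Top2a, Egr2 and Hbb in CPM on a log axis, with a point for each of the 3 libraries of control, PSCI and taVNS and a bar at the group mean. Gfap averages 946 CPM in control, 6110 in PSCI and 1040 in taVNS, and Hbb 52.6, 25.1 and 113 CPM.

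Of 15 measured genes of the reactive astrocyte list, 11 rose in PSCI and none fell (0), and 13 rose when adjusted over the list alone. The list was called with adjusted p = 7.6e-11 at the preset correlation, and adjusted p = 0.25 with an estimated correlation. Its level was highest in PSCI replicate 2 (5.72 log2 CPM), where the meningeal list also stood at 4.81. The other PSCI libraries had 4.15 and 4.97, against 1.89 to 2.33 in control. Besides Gfap (log2 fold change 2.69 ± 0.324 SE, adjusted p = 0.0023) and Vim (5.07 ± 0.51, adjusted p = 0.00104), Serping1, the inhibitor of complement C1, rose 14.1-fold to 39.9 ± 7.44 CPM. S1pr3, a receptor for sphingosine 1-phosphate, rose 8.36-fold from 6.87 ± 1.19 to 57.5 ± 11.4 CPM (adjusted p = 1.04e-04). Lcn2, an iron-carrier binding protein of reactive astrocytes, rose by 5.28 ± 0.701 on the log2 scale, and Timp1, an inhibitor of metalloproteinases, by 5.54 ± 0.851. Among homeostatic astrocyte genes, Aqp4, the water channel of astrocyte endfeet, rose 1.52-fold from 658 ± 68.5 to 1000 ± 75 CPM (adjusted p = 0.0159; 0.0734 at most over the alternatives, lost without control replicate 3 or PSCI replicate 3).

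In the microglia and macrophage list 13 of 18 measured genes rose and none fell (0); adjusted over the list alone 14 rose and 1 fell. The list had adjusted p = 4.0e-09 at the preset correlation and adjusted p = 0.34 with an estimated correlation. All 3 genes of complement C1q rose: C1qa 3.16-fold, C1qb 4.28-fold and C1qc 4.78-fold, and each kept its call under every alternative. Aif1, the microglial calcium-binding protein also called Iba1, rose from 11.8 ± 1.92 to 32.9 ± 10.2 CPM, and Itgam, an integrin of myeloid cells, 6.09-fold to 51.7 ± 13.5 CPM. Cd68, a lysosomal protein of phagocytes, rose from 0.448 ± 0.246 to 8.89 ± 6.06 CPM (adjusted p = 0.0118; 0.0928 at most over the alternatives, and lost without control replicate 1 or 3). Lgals3, a galectin of phagocytic cells, rose by 7.43 ± 1.03 on the log2 scale. The levels of the list per library were highest in PSCI replicate 2 (5.95 log2 CPM), where the meningeal list also stood at 4.81, and the other PSCI libraries had 4.79 and 5.67 against 3.34 to 3.86 in control.

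Among genes of neurogenesis and cell division 8 of 14 rose and none fell (0), and 9 rose when adjusted over the list alone. The list had adjusted p = 1.5e-05 at the preset correlation and adjusted p = 0.27 with an estimated correlation. The members that rose include genes of the cell cycle: Top2a (5.05 ± 0.475, adjusted p = 7.24e-04), Cdk1, the mitotic kinase, which rose 22.3-fold to a mean of 17.1 CPM, and Mki67, the proliferation antigen, which rose 6.08-fold to 93.5 ± 51.1 CPM. Draxin, a guidance protein of developing axons, rose 3.56-fold to 21.8 ± 6.45 CPM. The microtubule protein of young neurons Dcx was at 55.5 ± 16.2 CPM in control and 46.5 ± 7.65 CPM in PSCI.

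The cytokine and NF-kB list had 9 of 11 genes higher in PSCI and none lower (0), with 9 higher and 1 lower when adjusted over the list alone. It had adjusted p = 5.9e-08 at the preset correlation and adjusted p = 0.15 with an estimated correlation. Il18, a cytokine released by the inflammasome, rose 5.75-fold from 2.82 ± 0.568 to 16.2 ± 1.61 CPM. Counts and RPKM disagreed for 3 of its members, Nfkbia, Nlrp3 and Tlr4, whose counts rose 4.33-fold, 7.66-fold and 6.3-fold, and without them 6 of 8 rose. In the apoptosis and autophagy list 11 of 18 genes rose and 1, Sqstm1, fell, with 12 and 1 adjusted over the list alone. It had adjusted p = 1.1e-10 at the preset correlation and adjusted p = 0.0288 with an estimated correlation. Counts and RPKM disagreed for 8 of these members, among them Atg5, Bax, Bcl2, Becn1, Casp9, Sqstm1 and Ulk1. Only 17 of the 18 members had enough counts and RPKM to be compared, so the other 10 include a member that was not examined. Of the other 10 members, 4 rose, among them Bad, Casp8 and Fas, and the list then had adjusted p = 3.2e-04 at the preset correlation and adjusted p = 0.26 with an estimated correlation. Casp8, the initiator caspase of death receptors, rose by 3.28 ± 0.29 on the log2 scale, and Fas, a death receptor, by 2.14 ± 0.434.

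Of 20 interferon and antigen presentation genes 5 rose, or 10 adjusted over the list alone, with adjusted p = 0.0011 at the preset correlation and adjusted p = 0.43 with an estimated correlation. Psmb9, a subunit of the immunoproteasome, rose 3.02-fold to 6.23 ± 1.67 CPM, and RT1-A2, a class I histocompatibility gene, 2.48-fold to 68.1 ± 17.6 CPM. Psmb8 and RT1-Da rose 4.16-fold and 18.0-fold, and their adjusted p reached 0.0795 and 0.207 over the alternatives, being lost without any 1 control library or without PSCI replicate 3. The level of this list was 3.69 log2 CPM in PSCI replicate 2, beside its high meningeal level, and 2.55 and 3.35 in the other PSCI libraries. In the endothelium and pericyte list 1 of 14 genes, Tie1, rose, and 0 adjusted over the list alone. The list had adjusted p = 0.0072 at the preset correlation, adjusted p = 0.60 with an estimated correlation and 0.0864 without control replicate 1. The call of Tie1 was lost in every fit that left out 1 library except those without control replicate 2 or PSCI replicate 1 (up to 0.144). The metallothioneins Mt1 and Mt2A of the glucocorticoid list rose 10.3-fold and 7.84-fold. Tsc22d3 of the same list fell 1.94-fold from 103 to 53 CPM (adjusted p = 0.0120), a call lost without control replicate 2 or 3 (up to 0.057). Foxj1, the transcription factor of ciliated cells, rose 4.79-fold from 5.28 ± 1.05 to 25.4 ± 3.53 CPM, while Ttr, the abundant transcript of the choroid plexus, was at 3.67 ± 4.33 and 2.17 ± 3.42 CPM. Hspb1, a small heat shock protein, rose 50.2-fold to 117 ± 111 CPM (adjusted p = 0.0040, and 0.057 with limma-voom), and Bag3, a co-chaperone, 2.25-fold to 31.8 ± 8.43 CPM.

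Of 20 immediate early genes 5 fell in PSCI and none rose (0), with 7 lower when adjusted over the list alone. The list had adjusted p = 4.2e-05 at the preset correlation and adjusted p = 0.15 with an estimated correlation. Npas4, a transcription factor induced by neuronal activity, fell 15.9-fold to 0.436 ± 0.0865 CPM (adjusted p = 0.0079), and Egr2 fell 8.37-fold (adjusted p = 0.0080). Nr4a2 fell 2.34-fold from 65.4 ± 8.92 to 27.9 ± 3.05 CPM and Nr4a3 2.34-fold from 61.8 ± 6.29 to 26.5 ± 10.2 CPM; the call of Nr4a3 was lost without any 1 control library or PSCI replicate 3, with adjusted p up to 0.0964. Bdnf, a growth factor of neurons, was at 46.5 ± 10.6 CPM in control and 39.7 ± 32.9 CPM in PSCI (adjusted p = 0.861).

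In the synaptic list 2 of 18 genes fell, 5 adjusted over the list alone, with adjusted p = 4.2e-05 at the preset correlation and adjusted p = 0.27 with an estimated correlation. Cplx1, a regulator of vesicle fusion, fell 1.52-fold from 436 ± 13.4 to 287 ± 10.4 CPM (adjusted p = 0.0082), and Rab3a, a vesicle GTPase, 1.36-fold to 330 ± 10.7 CPM (adjusted p = 0.0140, and 0.0731 at most over the alternatives, lost without control replicate 3). Of 23 oxidative phosphorylation genes 3 fell, 6 adjusted over the list alone (adjusted p = 2.5e-06 at the preset correlation, adjusted p = 0.44 with an estimated correlation). These were Ndufs3, Ndufb9 and Uqcrc2, subunits of complexes of the respiratory chain, which fell 1.3-fold, 1.48-fold and 1.35-fold, and each lost its call without control replicate 3, with adjusted p of at most 0.075, 0.0569 and 0.0525 over the alternatives. Ndufs3 and Uqcrc2 lost it also without PSCI replicate 3, and Ndufs3 without control replicate 1. Of 15 interneuron genes 2 fell, among them Erbb4, a neuregulin receptor, by 1.52-fold. Adjusted over the list alone 6 fell and 1 rose, and the list had adjusted p = 0.0019 at the preset correlation and adjusted p = 0.32 with an estimated correlation. The call of Erbb4 was lost without control replicate 2, control replicate 3 or PSCI replicate 3, with adjusted p up to 0.0822. The clock list, with 1 member higher (Bhlhe41) and 1 lower (Nr1d1), or 1 and 3 adjusted over the list alone, had adjusted p = 0.0028 at the preset correlation and adjusted p = 0.37 with an estimated correlation. The call of Nr1d1 was lost without any 1 library other than PSCI replicate 1 (up to 0.143). That of Bhlhe41 was lost without control replicate 2 or 3, PSCI replicate 3 or any 1 taVNS library (up to 0.15). The red blood cell list had a median log2 fold change of -1.37 with none of its 7 members past the threshold (0, and 0 adjusted over the list alone), adjusted p = 0.0012 at the preset correlation and adjusted p = 0.37 with an estimated correlation.

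The largest rises by the fixed rule were of genes close to absent in control. Cd8a, a T cell co-receptor, and E2f8, a cell cycle transcription factor, had no count in control (0) and were at least 62.2-fold and at least 56.7-fold higher in PSCI against a floor of 3 counts over the group. Without PSCI replicate 2 these bounds were at least 23.0-fold and at least 37.1-fold, and Cd8a was at 0.341, 9.75 and 2.87 CPM in the 3 PSCI libraries. With 1 control count each, the ratio was 384 (95% counting interval 68.5 to 15200) for Lbp, the lipopolysaccharide-binding protein, 303 (54 to 12000) for Igsf7 and 136 (24 to 5400) for Atp8b4. With 3 control counts it was 75.2 (25.4 to 367) for Tlr8, an endosomal RNA sensor, and 61.0 (20.6 to 298) for Bcl3, an NF-kB cofactor. PSCI replicate 2 raised several of these: without it the ratio was 32.4 (5.26 to 1330) for Lbp, 84.5 (14.6 to 3390) for Atp8b4 and 27.7 (9.02 to 138) for Bcl3. Lbp was at 0.750, 25 and 0.783 CPM in the 3 PSCI libraries. Igsf7 was at 0.409, 10.6 and 10.1 CPM, with a ratio of 227 (40.1 to 9010) without PSCI replicate 2 and 438 (78.1 to 17400) without PSCI replicate 1. Of 86 named calls, the fitted folds of 10 moved by over 1.5 times without PSCI replicate 2, namely Cd8a, E2f8, Spp1, Lbp, Lgals3, Atp8b4, Ccl2, Bcl3, Hspb1 and Top2a. Those of 6 did without control replicate 2 (Lgals3, Atp8b4, Ccl2, Tlr8, Pimreg and Synpo2), those of 2 without control replicate 1 (Lbp and Igsf7) and that of 1 without control replicate 3 (Bcl3). Spp1, the secreted phosphoprotein osteopontin, rose from 0.587 ± 0.331 to 260 ± 239 CPM, and Ccl2, a monocyte chemokine, from 0.142 ± 0.122 to 10 ± 9.93 CPM. Pimreg rose from 0.165 ± 0.107 to 9.94 ± 6.06 CPM and Cd14, a co-receptor for lipopolysaccharide, from 0.333 ± 0.0931 to 18.8 ± 8.55 CPM. Of these 12 rises, which include Lgals3, 5 kept their call under every alternative, namely E2f8, Atp8b4, Tlr8, Pimreg and Cd14. The calls of Cd8a, Lbp, Igsf7, Ccl2 and Bcl3 were each lost without any 1 control library, with adjusted p of up to 0.109, 0.142, 0.118, 0.172 and 0.0657. That of Cd8a was also lost without PSCI replicate 2 or 3 or taVNS replicate 1 or 2, and that of Lbp without any 1 taVNS library. Spp1 and Lgals3 lost theirs with limma-voom (0.202 and 0.106).

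Among the 12 largest falls, beside Npas4, Egr2 and Sqstm1, were Agt, the precursor of angiotensin, which fell 3.1-fold from 205 ± 6.91 to 66.1 ± 21.1 CPM, and Tlcd1, a membrane lipid protein, which fell 3.18-fold from 12.1 ± 0.624 to 3.80 ± 0.252 CPM (adjusted p = 4.19e-04). Krt2, a keratin, fell 3.42-fold from 14.0 ± 1.22 to 4.07 ± 0.808 CPM. These 6 kept their calls under every alternative in which they were tested. Sqstm1, the autophagy receptor p62, was not tested without the genes that disagree, being 1 of them. Its counts fell by 2.47 on the log2 scale and its RPKM by 0.74. The remaining 6 were Piezo2, Cldn1, tGap1, Efcab3, Apoc1 and Htra4, with falls of 3.0-fold to 6.14-fold, and their calls were lost without control replicate 3, with adjusted p of up to 0.0705, 0.148, 0.0715, 0.132, 0.0517 and 0.157 over the alternatives. Except for Apoc1 they were lost also without control replicate 1 or PSCI replicate 3. Further losses came without control replicate 2 (Piezo2, Cldn1, tGap1 and Htra4), PSCI replicate 1 (Cldn1, Efcab3 and Htra4), PSCI replicate 2 (Htra4), taVNS replicate 1 (Cldn1, Efcab3 and Htra4), taVNS replicate 2 (Efcab3) and taVNS replicate 3 (Cldn1 and Efcab3). No gene of the excitatory neuron, dentate granule cell, oligodendrocyte, acetylcholine, monoamine or striatum lists passed the threshold (0 over all genes by edgeR). The vesicular glutamate transporter Slc17a7 was at 1790 ± 29.8 and 1620 ± 364 CPM, the GABA enzyme Gad1 at 214 ± 29.9 and 178 ± 34.3 CPM, the myelin gene Mbp at 5400 ± 1830 and 3930 ± 1980 CPM and the nicotinic receptor Chrna7 at 11 ± 2.80 and 9.06 ± 2.01 CPM.

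The 16 lists that were not called in PSCI against control had adjusted p between 0.0941 and 0.783 at the preset correlation. They were excitatory neurons, dentate granule cells, homeostatic astrocytes, oligodendrocytes, their precursors, choroid plexus, meninges, thalamus, striatum, neocortex, acetylcholine, monoamines, neurotrophic factors, glucocorticoid response, heat shock and hypoxia. In 4 of these the median, mean and test differed in sign, and in 0 of the 13 called lists. Adjusted over the list alone, 3 homeostatic astrocyte genes were higher and 4 lower, 3 hypoxia genes higher, 2 glucocorticoid genes higher and 1 lower, 2 heat shock genes higher and 2 precursor genes lower. Among neocortex genes 1 was higher and 1 lower, and 1 was higher in each of the choroid plexus, meningeal, neurotrophic and thalamus lists, with 0 in the other 6 lists. In the meningeal list Igfbp2 alone rose (1 of 13), 9.75-fold, with a median of 1.86 over the list. At the preset correlation the list was called without PSCI replicate 3 (0.0335), taVNS replicate 1 (0.0473) or taVNS replicate 3 (0.0085), and with the 6 libraries alone (0.0091). With all libraries and an estimated correlation it had adjusted p = 0.67. Without PSCI replicate 1 the excitatory neuron list (adjusted p = 0.0259) and the dentate granule cell list (0.0250) were called lower at the preset correlation. The monoamine list was called lower without PSCI replicate 2 (0.0436). With all libraries and an estimated correlation adjusted p was 0.72 for excitatory neurons, 0.60 for dentate granule cells and 0.35 for monoamines. The call of Igfbp2 itself was lost without any 1 control library, PSCI replicate 2 or PSCI replicate 3 (up to 0.122).

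The comparison of taVNS with PSCI asks what differs between stimulated and unstimulated impaired rats. Of the gene lists, 10 of 15 reactive astrocyte, 8 of 18 microglia, 7 of 11 cytokine and 8 of 14 cell division genes fell in taVNS against PSCI, and 4 of 7 red blood cell genes rose. With an estimated correlation none of these 5 lists was called (adjusted p = 0.14 to 0.61). Gfap fell 5.85-fold to 1040 ± 292 CPM (adjusted p = 0.0045), Vim from 860 to 55.7 ± 33.8 CPM and Top2a 28.3-fold to 2.13 ± 0.408 CPM (adjusted p = 0.00117). Hbb, a haemoglobin beta chain, rose 4.5-fold from 25.1 ± 15.8 to 113 ± 61.0 CPM. In all 854 genes passed the test, 125 higher and 729 lower, of which 26 and 529 changed at least 2-fold. The count was 488 without control replicate 2, 1707 without PSCI replicate 1, 375 without PSCI replicate 3, 172 without taVNS replicate 1, 254 without taVNS replicate 2 and 313 without taVNS replicate 3. It was 250 with the 6 libraries alone, 480 with limma-voom and 1560 with DESeq2. The split was 420 higher and 1140 lower with DESeq2, and 84 and 582 with limma on log2 RPKM with 0.1 added.

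Of the 15 reactive astrocyte genes 10 fell in taVNS against PSCI, 11 adjusted over the list alone, with adjusted p = 8.7e-09 at the preset correlation and adjusted p = 0.25 with an estimated correlation. S1pr3 fell 5.8-fold to 9.92 ± 1.85 CPM (adjusted p = 3.74e-04), and Lcn2 30.5-fold to 0.484 ± 0.232 CPM, whose adjusted p of 0.0057 became 0.0688 with limma-voom. Complement C3, which is on the same list, was at 38.1 ± 12.5 CPM in PSCI and 58.0 ± 23.2 CPM in taVNS. Aqp4 fell 1.53-fold, and its call was lost without PSCI replicate 3, taVNS replicate 1 or taVNS replicate 3 (up to 0.124). The glutamine synthetase Glul fell 1.67-fold, a call lost without any 1 library other than PSCI replicate 1 (up to 0.125).

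Among microglia and macrophage genes 8 of 18 fell and 1, Tmem119, rose, with 11 and 2 adjusted over the list alone (adjusted p = 3.5e-05 at the preset correlation, adjusted p = 0.61 with an estimated correlation). C1qa fell 2.28-fold, C1qb 3.89-fold and C1qc 3.95-fold, all kept under every alternative, and Gpnmb, a glycoprotein of phagocytes, 11.8-fold to 17.1 ± 6.57 CPM, where the call was lost without taVNS replicate 1 or 2 (up to 0.0645). Tmem119, a marker of resident microglia, rose by 0.95 ± 0.192 on the log2 scale. Aif1 fell 1.97-fold to 16.7 ± 1.87 CPM with adjusted p = 0.0366, but the call was lost in 8 of the 9 fits that left out 1 library, all but that without PSCI replicate 1, and adjusted p reached 0.141. Cd68, at 8.89 ± 6.06 and 2.53 ± 1.37 CPM, did not pass (adjusted p = 0.158). The meningeal level of 4.81 in PSCI replicate 2 and 5.12 in taVNS replicate 3 stood beside microglial levels of 5.95 and 4.66 in these libraries.

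In the cell division list 8 of 14 genes fell, 9 adjusted over the list alone, with adjusted p = 1.1e-05 at the preset correlation and adjusted p = 0.25 with an estimated correlation. Cdk1 fell 25.1-fold to 0.670 ± 0.135 CPM and Mki67 5.44-fold to 17.2 ± 3.78 CPM, and Ccna2, a cyclin of S phase and mitosis, 22.2-fold to 0.671 ± 0.0371 CPM (0.072 with limma-voom). Of 11 cytokine and NF-kB genes 7 fell, 9 adjusted over the list alone (adjusted p = 5.0e-08 at the preset correlation, adjusted p = 0.14 with an estimated correlation), among them Il18, which fell 4.53-fold to 3.58 ± 1.29 CPM. Without Nfkbia, Nlrp3 and Tlr4, whose counts and RPKM disagree, 4 of 8 fell. Of 18 apoptosis and autophagy genes 10 fell and Sqstm1 rose, 12 and 1 adjusted over the list alone, with adjusted p = 2.5e-12 at the preset correlation and adjusted p = 0.0183 with an estimated correlation. Of its 10 members not found to disagree, which include a member too low to be compared, 3 fell (Bad, Casp8 and Fas). These 10 had adjusted p = 9.0e-05 at the preset correlation and adjusted p = 0.25 with an estimated correlation.

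Of 7 red blood cell genes 4 rose past the threshold, and 7 adjusted over the list alone, with adjusted p = 1.2e-06 at the preset correlation and adjusted p = 0.25 with an estimated correlation. Hba-a1, a haemoglobin alpha chain, rose 4.03-fold to 104 ± 50.5 CPM, Hbb-bs 7.14-fold to 6.13 ± 2.99 CPM and Alas2, the haem synthesis enzyme of erythroid cells, 8.18-fold to 2.04 ± 0.645 CPM. All 4 calls were lost without taVNS replicate 1, with adjusted p of up to 0.104 for Hbb, 0.0942 for Hba-a1, 0.0748 for Hbb-bs and 0.144 for Alas2. Those of Hbb, Hbb-bs and Alas2 were lost also without taVNS replicate 2, and those of Hba-a1 and Alas2 without taVNS replicate 3. Leaving out any 1 control library ended those of Hbb and Alas2, control replicate 2 that of Hba-a1, PSCI replicate 1 that of Alas2, and PSCI replicate 2 those of Hbb and Hba-a1. The level of the list in taVNS replicate 1 was 4.32 log2 CPM, against 2.73 and 3.45 in the other taVNS libraries, 2.45 to 2.8 in control and 0.843 to 1.95 in PSCI. Of 18 synaptic genes Cplx1 rose 1.36-fold to 390 CPM (adjusted p = 0.0396, and up to 0.134, lost without any 1 control or taVNS library or without PSCI replicate 2 or 3), and 2 rose adjusted over the list alone. The list had adjusted p = 3.5e-05 at the preset correlation and adjusted p = 0.25 with an estimated correlation. The oxidative phosphorylation list, with none of 23 members past the threshold (0, also adjusted over the list alone), had adjusted p = 0.0037 at the preset correlation and adjusted p = 0.72 with an estimated correlation. Of 15 clock genes Dbp and Nr1d1 rose, 1.64-fold and 1.48-fold, 2 also adjusted over the list alone, with adjusted p = 0.0034 at the preset correlation and adjusted p = 0.56 with an estimated correlation. The call of Dbp was lost without control replicate 2, PSCI replicate 3, taVNS replicate 1 or taVNS replicate 3 (up to 0.105), and that of Nr1d1 without any 1 library other than PSCI replicate 1 (up to 0.126).

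The 12 largest falls in taVNS against PSCI held Bub1b, a checkpoint kinase, which fell 27.0-fold to 0.508 ± 0.198 CPM, Cks2 25.3-fold, and Parpbp 32.5-fold to 0.116 ± 0.0394 CPM, along with Cdk1, Top2a and E2f8. Ccl2 was lower with a ratio of 442 (95% counting interval 78.9 to 17500, 1 count in taVNS), which was 207 (36.6 to 8250) without PSCI replicate 2. Of 65 named calls, the fitted folds of 11 moved by over 1.5 times without PSCI replicate 2: Ccna2, Cks2, Lgals3, Bub1b, E2f8, Spp1, Top2a, Lcn2, Parpbp, Hspb1 and Ccl2. Those of 5 did without PSCI replicate 3 (Alas2, Hbb-bs, Hbb, Npy and Trh), and those of 3 without taVNS replicate 3 (Lgals3, E2f8 and Ccl2). Trh, the thyrotropin-releasing hormone, fell 65.2-fold from 41.2 ± 36.3 to 0.624 ± 0.116 CPM, Hspb1 34.1-fold to 3.43 ± 0.744 CPM, Spp1 27.8-fold to 9.32 ± 6.68 CPM and Lgals3 25.5-fold to 2.92 ± 2.12 CPM. Of these 12, counting Lcn2, 3 kept their call under every alternative (Cdk1, Top2a and Parpbp). The calls of Trh, Ccl2, Cks2, Lgals3, E2f8 and Spp1 were each lost without taVNS replicate 1 or 2, with adjusted p of up to 0.273, 0.12, 0.0825, 0.108, 0.123 and 0.174. Those of Trh, Ccl2, Cks2 and Spp1 were lost also without taVNS replicate 3, those of E2f8 and Spp1 without PSCI replicate 3, and that of Spp1 without PSCI replicate 2 or any 1 control library. Bub1b and Hspb1 lost theirs with limma-voom alone (0.0525 and 0.0751).

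Of the 12 largest rises 3 kept their call under every alternative in which they were tested: Krt2, which rose 3.84-fold to 15.6 ± 4.48 CPM, Gzmm, a granzyme, 3.45-fold from 1.73 ± 0.171 to 5.99 ± 0.646 CPM (adjusted p = 0.00267), and Sqstm1, whose counts rose by 2.39 on the log2 scale and whose RPKM rose by 0.69 on the same scale. Sqstm1 was not tested in the setting without the genes whose counts and RPKM disagree. Col11a2, a fibrillar collagen, rose 3.02-fold to 274 ± 29.3 CPM, Piezo2, a mechanosensitive channel, 3.09-fold to 20.6 ± 2.88 CPM, Mroh7 3.46-fold and Tmprss7 3.46-fold. The calls of Col11a2, Piezo2, Mroh7 and Tmprss7 were lost without taVNS replicate 1, with adjusted p of up to 0.0621, 0.11, 0.0687 and 0.0766. Those of Piezo2 and Tmprss7 were lost also without PSCI replicate 3, taVNS replicate 2 or taVNS replicate 3, and that of Piezo2 without control replicate 2. The retinoic acid hydroxylase Cyp26b1 and tGap1 rose 2.89-fold and 4.2-fold, with adjusted p up to 0.141 and 0.0789, and both were lost without PSCI replicate 3, taVNS replicate 1 or taVNS replicate 3. That of Cyp26b1 was lost also without control replicate 2 or 3, PSCI replicate 1 or 2, or taVNS replicate 2.

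The 20 lists not called in taVNS against PSCI had adjusted p between 0.0511 and 0.902 at the preset correlation, and in 7 of them the median, mean and test differed in sign, against 0 of the 9 called. Adjusted over the list alone, 3 interneuron genes were higher and 1 lower, 2 precursor genes higher and 1 lower, and 1 neocortex gene higher. Lower were 2 genes each of the heat shock, homeostatic astrocyte, hypoxia and neurotrophic lists and 1 each of the choroid plexus and oligodendrocyte lists. Without taVNS replicate 3 the meningeal list was called lower (adjusted p = 0.0046). Without PSCI replicate 2 the oligodendrocyte list was called lower (0.0111) and the striatum and interneuron lists higher (0.0401 and 0.0192). The interneuron list was called higher also without taVNS replicate 2 (0.0080). Without PSCI replicate 1 the dentate list was called higher (0.0148) and the heat shock and hypoxia lists lower (0.0262 and 0.0224). The dentate and hypoxia lists were called also with the replicate block (0.0489 each), and the hypoxia list with the stricter filter (0.0494) or without the genes whose counts and RPKM disagree (0.0468). All list calls in this paragraph are at the preset correlation. With all libraries and an estimated correlation none of the 20 lists was called. These lists were the excitatory, dentate, interneuron, homeostatic astrocyte, oligodendrocyte, precursor, endothelium, choroid plexus, meningeal, thalamus, striatum, neocortex, immediate early, interferon, acetylcholine, monoamine, neurotrophic, glucocorticoid, heat shock and hypoxia lists. In the glucocorticoid list 4 of 14 genes fell (4 adjusted over the list alone): Mt1 8.64-fold, Mt2A 9.55-fold, Cdkn1a 2.86-fold and Sgk1 2.05-fold, the last with adjusted p up to 0.108 and lost without any 1 taVNS library, control replicate 2, control replicate 3 or PSCI replicate 3. Cdkn1a was lost without taVNS replicate 1 or 2 (up to 0.0732). The list was called lower without PSCI replicate 2 (adjusted p = 0.0042), PSCI replicate 3 (0.0120) or taVNS replicate 2 (0.0291). It was called also with no filter (0.0484), the stricter filter (0.0494), the block (0.0446) or without the genes whose counts and RPKM disagree (0.0468). Foxj1 fell 3.4-fold to 7.45 ± 0.477 CPM and Bag3 2.36-fold to 13.4 ± 2.30 CPM, and the call of Bag3 was lost without taVNS replicate 1 (up to 0.0646). Among interneuron genes the neuropeptide Npy fell 3.52-fold from 43.3 ± 29.6 to 12.3 ± 1.74 CPM (adjusted p = 0.0417, up to 0.138, lost without any 1 control or taVNS library or PSCI replicate 3). Chrna7, the nicotinic receptor subunit of the cholinergic anti-inflammatory pathway, was at 9.06 ± 2.01 CPM in PSCI and 13.6 ± 2.81 CPM in taVNS (adjusted p = 0.211).

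The comparison of taVNS with control asks how far the stimulated rats differ from rats without stroke. No gene passed the edgeR test (0 of 14840), and the smallest adjusted p was 0.9999. An unadjusted p under 0.05 was found for 557 genes, where 742 are expected by chance. This number was 768 of 14451 genes with the 6 libraries alone. Leaving out 1 library gave from 292 of 15033 (taVNS replicate 3) to 773 of 14936 (PSCI replicate 2). The main fit takes its spread also from the PSCI libraries, which varied most. A count under chance therefore does not show that taVNS and control are alike. The 6 genes with the smallest p were C3, C4a, C2, Bst2, Aspg and Nr4a2, of which 3 encode complement components. C3 was at 11.8 ± 4.95 CPM in control and 58.0 ± 23.2 CPM in taVNS, C4a at 16.3 ± 4.59 and 51.8 ± 18.2 CPM, and C2 at 10.3 ± 0.601 and 26.0 ± 7.82 CPM. Bst2, an interferon-induced membrane protein, was at 2.71 ± 0.502 and 6.70 ± 1.09 CPM, Aspg at 0.448 ± 0.174 and 2.01 ± 0.478 CPM, and Nr4a2 at 65.4 ± 8.92 and 37.1 ± 7.37 CPM. DESeq2 called 7 genes, these 6 and LOC689268, limma-voom called 0, and edgeR called 1 gene, RGD1563601 (log2 fold change -2.97), without taVNS replicate 3.

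At the preset correlation 11 lists were called in taVNS against control, though no member of them passed the threshold over all genes, and none of the 11 held with an estimated correlation (0; the smallest adjusted p was 0.0559 with an estimated correlation, for the immediate early genes). Higher in taVNS were microglia and macrophages (median log2 fold change 0.48, adjusted p = 8.3e-11, and adjusted p = 0.48 with an estimated correlation), interferon and antigen presentation (0.69, 6.1e-09 and 0.48) and endothelium (0.42, 1.7e-06 and 0.48). So were reactive astrocytes (0.40, 3.0e-04 and 0.57), red blood cells (1.10, 2.8e-04 and 0.48), meninges (1.58, 0.0043 and 0.78) and cytokines (0.40, 0.0168 and 0.48). Lower were immediate early genes (-0.62, 8.3e-11 and 0.0559), oxidative phosphorylation (-0.12, 2.0e-05 and 0.61), glucocorticoid response (-0.17, 2.8e-04 and 0.48) and interneurons (-0.08, 0.0149 and 0.48). Adjusted over the list alone, 6 immediate early genes, 1 glucocorticoid gene, 2 reactive astrocyte genes and 1 cytokine gene passed, and 0 in the other 7 called lists. The immediate early gene Junb was at 52.6 ± 7.84 CPM in control and 27.7 ± 2.57 CPM in taVNS, and Sgk1, a kinase induced by glucocorticoids, at 136 ± 13.1 and 69.2 ± 7.22 CPM. Itgam was at 8.46 ± 3.30 and 20.0 ± 4.40 CPM, Serping1 at 2.81 ± 0.894 and 8.68 ± 5.13 CPM, and Gfap at 946 ± 288 and 1040 ± 292 CPM.

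Single libraries decided some of these list calls. Without taVNS replicate 3, the library with the high meningeal level, the meningeal list had a mean log2 fold change of 0.01 and adjusted p = 0.986, and the cytokine list adjusted p = 0.0814, which was 0.0740 without control replicate 3. The red blood cell list had 0.0565 without taVNS replicate 1, the oxidative phosphorylation list 0.0649 without control replicate 1, and the interneuron list 0.0897 without control replicate 3 and 0.334 without taVNS replicate 2. With the stricter filter or the 6 libraries alone the interneuron list had 0.0778 and 0.0742. Without the genes whose counts and RPKM disagree the cytokine list had adjusted p = 0.108. The 18 other lists, which include the apoptosis and autophagy, cell division, synaptic, clock and excitatory neuron lists, had adjusted p between 0.0518 and 0.972, with 0 members past when adjusted over the list alone. Of these the homeostatic astrocyte list was called lower without control replicate 3 (2.6e-04), PSCI replicate 1 (0.0136), PSCI replicate 3 (0.0487) or taVNS replicate 2 (0.0402). It was called lower also with the 6 libraries alone (0.0253), the block (0.0318) or the size factors of DESeq2 (0.0491). The excitatory neuron list was called lower without taVNS replicate 2 (0.0103), and the oligodendrocyte list without control replicate 3 (0.0092). These calls are at the preset correlation, and with all libraries and an estimated correlation no list was called (0). Median, mean and test differed in sign in 8 of the 18 other lists and in 0 of the 11 called.

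Set side by side, the changes in PSCI against control and in taVNS against PSCI went in opposite directions for nearly all called genes. Of the 1461 genes changed in PSCI, 1457 (99.73%) had the opposite sign in taVNS against PSCI. Both comparisons share the 3 PSCI libraries, and in 50 simulations of unchanged groups with the same sharing 86.1% of as many genes had opposite signs (range 83.7% to 87.7%). Past both thresholds were 753 genes, 664 higher in PSCI and then lower in taVNS and 89 lower and then higher. None passed both in the same direction (0). The immediate early genes averaged lower than control in both PSCI and taVNS. Their mean log2 fold change was -0.84 in PSCI against control, 0.018 in taVNS against PSCI (0 higher or lower past the threshold) and -0.822 in taVNS against control. Camera with an estimated correlation called the list in neither comparison with control (adjusted p = 0.15 and 0.0559). In taVNS against control no member passed the threshold over all genes. Across all 14840 genes, which are not independent replicates, Pearson's r between the log2 fold changes was -0.899 (simulated mean -0.495) and their covariance -0.423 (simulated mean -0.0536). The simulation gave all groups the same dispersion per gene, while the PSCI libraries varied most (median SD 0.217, against 0.167 in control and 0.149 in taVNS). A larger spread of the shared libraries would by itself give more opposite signs, so this reference may understate what sharing alone gives. The count of 753 was 721 leaving out the genes whose counts and RPKM disagree, 232 with the 6 libraries of each comparison alone, and 170, 247 and 308 without taVNS replicate 1, 2 and 3. It was 366 and 417 without control replicate 2 and 3, and 1505 and 349 without PSCI replicate 1 and 3.

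The 12 genes that the fixed rule gives for this reversal include Traf6, Casp9, Ulk1, Becn1, Map1lc3a, Rb1cc1, Bax, Gabarap and Ikbkb. For 10 of the 12, all but Tirap and Bad, counts and RPKM disagree in the PSCI libraries. Tirap, an adaptor of Toll-like receptors, was at 5.02 ± 0.162 CPM in control, 25.4 ± 0.645 in PSCI and 5.57 ± 0.394 in taVNS, and Bad, a promoter of apoptosis, at 25.5 ± 1.61, 99.9 ± 14.1 and 23.6 ± 1.03 CPM. The log2 folds and small SE of Tirap and Bad (2.34 ± 0.119 and 1.97 ± 0.116) are like those of the 10, such as 2.00 ± 0.0854 for Casp9. Among other genes not found to disagree, chosen after their values were seen, Tagln, a smooth muscle actin-binding protein, averaged 8.02 CPM in control, 120 in PSCI and 9.64 in taVNS. A2m, a protease inhibitor, averaged 21.2, 183 and 29.6 CPM, S100a4, a calcium-binding protein, 2.35, 78.0 and 3.71 CPM, and Cenpf, a centromere protein, 1.24, 22.1 and 1.53 CPM. Over the 1461 genes the median size of the log2 fold change was 1.29 in PSCI against control and 0.23 in taVNS against control. The first value is enlarged because the genes were chosen by that comparison. In taVNS against control 1198 of them (82%) kept the sign they had in PSCI, and the slope through 0 on the PSCI change was 21.9%. Both comparisons share the control libraries, which alone favours the same sign, and no simulated value was made for this.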

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

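The splits of the samples were planned, and all other tests in this part were chosen after the result was seen. Counts and RPKM disagreed by more than 0.25 (log2) in the PSCI libraries for 47 genes, against 6 in the control set and 2 in the taVNS set. The comparison used the deposited RPKM, which the comparisons of groups use only as an alternative, and its limits were chosen after 0.25, 0.3, 0.4 and 0.5 had been looked at. At 0.5 the numbers were 22, 0 and 0.

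The pattern is a disagreement of counts and RPKM in the PSCI libraries for 47 genes, such as Bcl2, whose counts rose by 2.32 (log2) while its RPKM fell by 2.20. The tables argue against a disagreement found in any 3 libraries, since 1 of the 84 sets, the PSCI set itself, reached 47 and the highest other had 13. Rounding of low values alone cannot give the pattern, since at the minimum RPKM it allows at most 0.148. The limit of 0.25 fixed in advance that the median deviation of 47 of 47 genes was larger, so this is a property of the rule and not a test. A change of isoform use would alter the length that RPKM divides by. Of the 22 genes past 0.5, 5 have 1 RefSeq transcript in GRCr8: Bcl2, Gabarap, Gabarapl2, Map1lc3a and Tlr4. Their median deviations were 4.96, 1.56, 2.17, 1.51 and 0.729 (log2). As far as that annotation holds, this argues against isoform use for these 5, and it stays open for the other genes. The bound for this test was changed, after the 5 had been seen, from at least 4 genes to more than 50% of the genes. The reasons were that the annotation is not the one the authors used and that the ratio of Gabarap also varies outside PSCI. By the changed bound the test does not decide for the 22 genes as a set. Different processing of the deposited tables was not tested and could also be the cause, and the files do not show which values, if either, came from the reads. The size of change of these 47 genes therefore cannot be relied on, nor its direction for the 9 whose counts and RPKM had opposite signs, among them Bcl2, Gabarapl2 and Pdk3.

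The pattern is the rise of glial and cell division genes in PSCI. The single library PSCI replicate 2, which also has a high meningeal level, does not carry it alone: 29 of the 32 called members of the microglia, reactive astrocyte and cell division lists stayed past the threshold without it. A lower share of neurons, with the other cell types in unchanged proportion, would raise the markers of all other types alike. The microglia median, however, lay 1.53 (log2) above the oligodendrocyte median, and per library the difference was at least -2.97 in PSCI and at most -3.84 in control. This argues only against such an even shift, and a loss of oligodendrocytes along with neurons was not tested. PSCI replicate 2 was the lowest library for excitatory neurons (6.65 log2 CPM, others 7.15 to 7.95) and for oligodendrocytes (6.78, others 7.17 to 7.92). The 10 splits of the 6 libraries are too few for a share under 0.05: 1 of 10, the real split, gave 1461 genes, and the highest other gave 0. An effect of the occlusion, lesion size and side, differences between rats and sham surgery stay open and untested.

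The pattern is that the taVNS libraries lie near the control libraries and away from PSCI. In taVNS against PSCI 1 of the 10 splits, the real one, gave 854 genes and the highest other 1, and in taVNS against control 10 of 10 gave as many as the real 0 (highest other 0), which are too few splits for a share under 0.05. Whether the taVNS libraries hold no injury signal cannot be told apart from a weak one: their lowest level of microglia and reactive astrocyte genes lay 2.04 SD of the control libraries above the control mean (3.36 log2 CPM, against 3.05 in the highest control library), under the limit of 3 SD set for it. An effect of the stimulation and a smaller lesion in these rats both stay open and untested. Neither lesion size nor hemisphere is given in the labels.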

How the results depend on the processing

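Leaving out the genes whose counts and RPKM disagree was chosen after the data were seen, and the other alternatives were planned. Of the 151 calls of named genes that were tried under the alternatives, 0 reversed and 78 were kept under every setting in which the gene was tested. Without the genes whose counts and RPKM disagree, 123 of the 151 were tested. Bcl2 and Gabarapl2 are not among the 151, and in their RPKM the PSCI change has the opposite sign (-2.20 and -0.29, against 2.32 and 1.85 in counts). Of the 33 list calls 0 were kept under every setting. Camera with an estimated correlation, which also uses fewer degrees of freedom, ended all but the apoptosis and autophagy calls. These ended in that setting without the genes that disagree. The median log2 fold change of all genes moved by at most 0.0454 under any setting.

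With the 6 libraries of a comparison alone, which leaves fewer residual degrees of freedom, 806 genes were called in PSCI against control, 250 in taVNS against PSCI, and 232 genes passed both thresholds in opposite directions. With DESeq2 the counts were 2278, 1560 and, in taVNS against control, 7. With a log2 fold limit of 1, which by construction keeps fewer genes, they were 877 and 555. In taVNS against PSCI limma-voom called 480 genes and the replicate block 518, and 486 genes passed both thresholds with the block. The other settings that used all 9 libraries stayed within 1.5 times the total counts of 1461 and 854 genes. The split moved more with log2 RPKM (0.1 added), where 174 genes were lower in PSCI against control, against 317 in the main fit.

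Leaving out each library in turn gave 548 to 2255 genes in PSCI against control (without control replicate 3 and without PSCI replicate 1), 172 to 1707 in taVNS against PSCI (without taVNS replicate 1 and without PSCI replicate 1) and 0 to 1 in taVNS against control (the 1 without taVNS replicate 3). The share of PSCI genes with the opposite sign in taVNS against PSCI ran from 99.06% to 100%, and the genes past both thresholds from 170 to 1505. The cause of these changes was not tested. Fewer libraries leave fewer degrees of freedom, but this alone does not account for the rises without PSCI replicate 1. There the counts went from 1461 to 2255 and from 854 to 1707.

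For the gene lists, camera with an estimated correlation called 1 list in PSCI against control, 1 in taVNS against PSCI and 0 in taVNS against control. Without genes whose counts and RPKM disagree, an estimated correlation called 0, 0 and 0. The cause was not tested for the DESeq2, limma-voom and block results. At this depth a gene with no count in a library lies under 0.195 to 0.218 CPM.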
